A study of Mus musculus with 6 samples.

How the data were processed

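RNA was sequenced from bone marrow neutrophils of male wild-type mice, isolated by flow cytometry per the series' design text, in 6 libraries: 3 from Control mice and 3 from mice taken through 4 weeks of chronic unpredictable mild stress (CUMS). Libraries were made from 1 µg of total RNA with a TruSeq RNA kit and read as pairs of 150 bp on an Illumina instrument, per the labels' protocols. Whether the kit kept strand, which surface markers set the sorting gate and whether each library came from its own animal are not given in the sources used here. The p-values of single genes and of library measures therefore reflect the spread between these samples, part of which may be technical.

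The submitters' processing notes name bcl2fastq 2.19, cutadapt 1.16.5, HISAT2 2.1, featureCounts 1.6.4 and DESeq2 2.11.40.6, and the build mm10. The deposited files hold 1 whole number per gene and library, and these were taken as estimated counts, not as counts of read pairs. The reason lies in the values: the numbers 4, 8, 12 and 16 occurred 1.89, 1.66, 1.41 and 1.38 times as often as their neighbours, so a read pair was worth about 4, the step that a coverage-based estimate gives when 2 reads of 150 bp are divided by an assumed read length of 75 bp. Moreover, 1588 of the 47561 rows carry identifiers of an assembled transcript (STRG). No tool that makes such identifiers is among those the notes name. The estimated counts sum to between 78845457 and 109757558 per library, or 19711364 to 27439390 read-pair equivalents after division by 4. Counting error is therefore larger than the numbers themselves would give, and the floor used for a gene listed at 0 is 3 read pairs, or 12 estimated counts, per library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

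Symbols were taken from the files. A GRCm38 gene table held 96.6% of the 47561 row symbols, and 1464 rows have locus names absent from it, so the annotation behind the files may be newer than that build. All coordinates, exon numbers, gene lengths and GC contents come from GENCODE M21 on GRCm38 and were matched by symbol. A GC value was found for 87.7% of the genes tested. Where 2 or more rows shared a symbol, the row with the highest total kept the name. Genes with near-identical copies (the H2-Q, haemoglobin and Ugt1a families, Ifit3 with Ifit3b, and Rps27rt) can exchange reads with those copies, so the value of each single member is uncertain. Reads of overlapping genes, antisense genes included, cannot be told apart without strand.

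The deposited values, already whole, entered edgeR 4.0.16 (R 4.3.3) as they stood. Genes were kept with filterByExpr at its defaults, which left 15778, libraries were scaled by TMM, and CUMS was compared with Control by the quasi-likelihood F test with group as the single term. Every adjusted p in the text is from that test with the Benjamini-Hochberg method at a threshold of 0.05, unless another test is named. CPM values are TMM-scaled, errors of log2 fold changes are standard errors derived from the F statistic, and errors of CPM are SD over 3 libraries. An SE of the median log2 fold change of a set of genes was instead taken by resampling those genes. It measures the spread between genes, not between libraries. Principal components used log2 CPM with a prior count of 2. Comparisons of single values used exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1. On simulated counts with the means, library sizes and spread of these libraries, and 200 changed genes (of at least 1 CPM) in each of 5 draws of about 15234 genes, the test recovered 82.6% of genes changed 2-fold and 44.2% of those changed 1.3-fold. Of 705 calls over the draws, 71 (10.1%) were false. That is more than the threshold of 0.05 aims at, so the false share among the genes called below may exceed it too.

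Before the data were examined, 28 gene lists were fixed, 19 on neutrophil biology and 9 of markers of other cell types. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists. Camera sets the genes of a list against all other genes tested. Its p-values at the preset correlation therefore do not measure the spread between libraries, however small they are. Camera with an estimated correlation and fry were run beside it. For a simulated shift of the cell cycle list by -0.5 on the log2 scale, camera called that list and 0 of the other 27. The simulated genes varied independently of each other, so this did not check camera on lists whose genes vary together. In the libraries themselves the estimated correlation reached 0.39 for the secondary granule list and 0.61 for the mitochondrially encoded list. Genes to be named were fixed by rule in advance: Elane, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out (for naming only) predicted or unnamed genes, pseudogenes, and immunoglobulin and T cell receptor segments, and, for each list, the 3 members with the smallest adjusted p or, where none passed, the 2 most abundant members. Further list members named beside these, and the genes of the lists on cholesterol and on MHC class I, were chosen after their values were seen. Some genes that the rule names are not reported here.

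Alternatives fixed in advance were DESeq2 1.42.0, limma-voom with and without sample quality weights, other scalings (RLE, library totals, upper quartile), no filter or a filter of 1 CPM in 3 libraries, leaving out haemoglobin, immunoglobulin and T cell receptor genes or mitochondrially encoded genes, corrections for GC content and gene length, the replicate number as a block, each library left out in turn, and other thresholds. An analysis of the deposited values divided by 4 was added after the files had been seen. Pairs of libraries of a group differed by 2.88 to 4.55 times the chi-square that counting on the read-pair scale would give, over 10933 to 10936 genes, so no library was a copy of another.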

Results

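Transcript abundance was measured in neutrophils sorted from the bone marrow of Control mice and of mice exposed to chronic unpredictable mild stress (CUMS), a rodent paradigm in which changing mild stressors are applied over 4 weeks to induce depression-like behaviour. The series title names neutrophil elastase (Elane) in connection with neutrophil entry into the brain, and the comparison asks which transcripts differ in the marrow pool of these cells after stress. Each group held 3 libraries. The deposited estimated counts summed to 78845457, 103483602 and 84814256 in Control replicates 1 to 3 and to 85799370, 109757558 and 107124855 in CUMS replicates 1 to 3, equal to about 19711364 to 27439390 read pairs. The first principal component held 25.8% of the variance and separated the groups without overlap (exact two-sided permutation p = 0.1, the smallest possible). The haemoglobin genes took 0.152% ± 0.028 of counts in Control and 0.261% ± 0.023 in CUMS (SD, n = 3 each, exact permutation p = 0.1). Shares of counts from mitochondrially encoded genes were 0.170% ± 0.0067 and 0.152% ± 0.010 (exact permutation p = 0.2).

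The sorted cells of CUMS mice held more transcript of the granule enzymes Elane and Mpo, of several MHC class I genes, of 13 of 40 interferon-response genes and of 9 of 18 erythroid markers. They held less transcript of 24 of 42 cell division genes, of 5 of 18 secondary granule genes and of 10 of 28 immediate early genes. In total, 710 of 15778 genes tested changed, 372 upward and 338 downward. Most changes were small: 488 of the 710 (68.7%) were below 1.5-fold, and 81 reached 2-fold (48 higher, 33 lower), 12 of them genes listed at 0 in every library of a group. All 710 had non-overlapping groups, as did 3618 (22.9%) of all genes tested, where chance gives 10%. The count fell to 305 without CUMS replicate 3, 341 without Control replicate 2, 348 without Control replicate 3, 350 without CUMS replicate 2 and 462 without Control replicate 1. Without CUMS replicate 1 it was 697, but only 532 of these were among the 710. DESeq2 called 1146 genes, 688 of them among the 710.

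**Figure D1:**
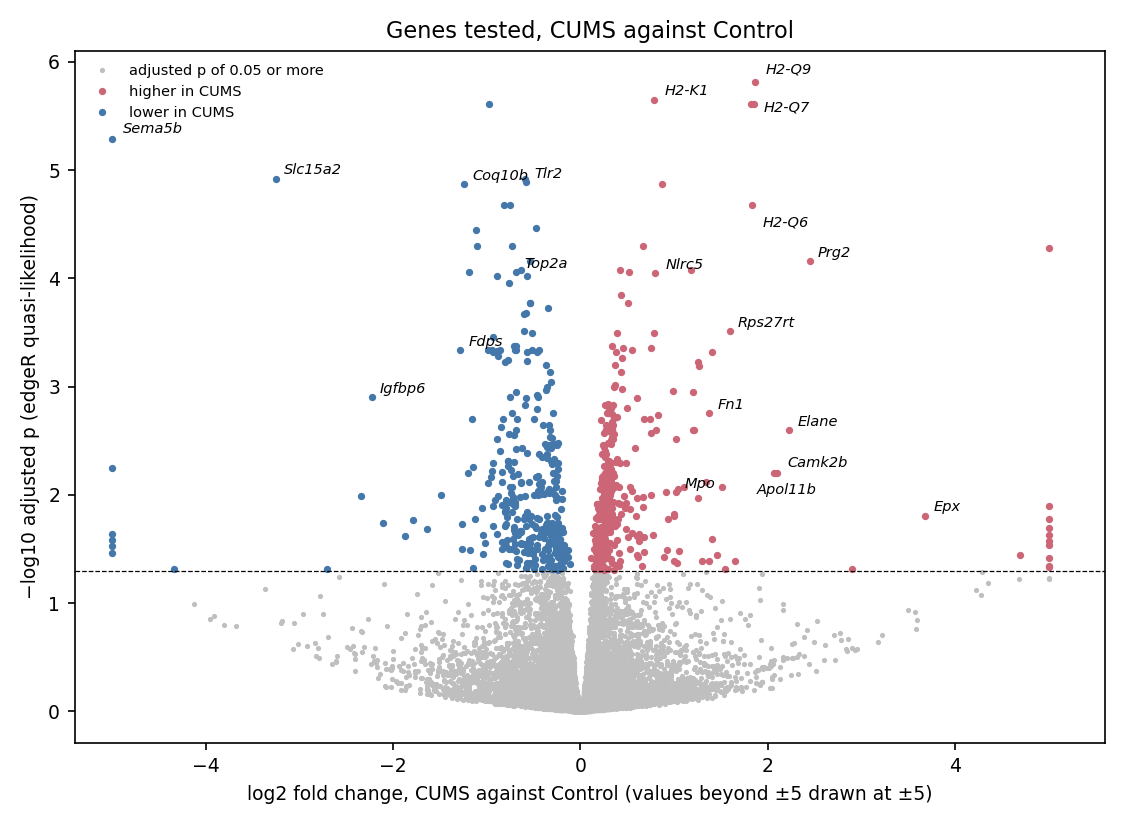
Each point is a gene, with its log2 fold change (CUMS against Control) on the x axis and -log10 of its edgeR adjusted p on the y axis, the dashed line marking an adjusted p of 0.05. Of 15778 genes, 372 were higher and 338 lower in CUMS. Elane lies at 2.23, and fitted values beyond ±5, which belong to genes listed at or near 0 in a group, are drawn at ±5.

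Elane, which encodes the serine protease neutrophil elastase stored in primary granules, was 4.68-fold higher in CUMS. Its abundance rose from 0.454 ± 0.133 CPM in Control to 2.13 ± 0.517 CPM in CUMS (SD, n = 3 each), a log2 fold change of 2.23 ± 0.32 (SE) with an adjusted p of 0.0025. All 3 CUMS libraries (1.65 to 2.67 CPM) lay above all 3 Control libraries (0.339 to 0.599 CPM), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. These levels are low: the estimated counts were 47, 35 and 36 in Control and 225, 183 and 223 in CUMS, about 8.75 to 11.8 and 45.8 to 56.3 read pairs, and Elane ranked between 9085 and 13130 among the 15778 genes. The gene (row symbol Elane) lies on the plus strand of chromosome 10 at 79886247 to 79888215 (GRCm38) and has 1 annotated protein-coding transcript with 5 exons. The values cover the whole gene, so no exon or UTR can be singled out.

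Among the other genes with large rises, Prg2, which encodes eosinophil major basic protein, rose from 0.885 ± 0.114 to 4.82 ± 0.708 CPM (SD, n = 3 each; log2 fold change 2.45 ± 0.21, adjusted p = 6.9e-05). It lies on chromosome 2 at 84980461 to 84983632 (GRCm38). Camk2b, a calcium/calmodulin-dependent kinase subunit, and Apol11b, an apolipoprotein L gene, were 4.32-fold and 4.21-fold higher in CUMS, from 0.440 ± 0.118 and 0.670 ± 0.318 CPM in Control (adjusted p = 0.0063 each). The non-classical MHC class I genes H2-Q9, H2-Q6 and H2-Q7 rose by 1.87 ± 0.085, 1.83 ± 0.13 and 1.82 ± 0.099, with H2-Q7 going from 6.62 ± 0.372 to 23.4 ± 1.88 CPM. H2-Q6 (35424850 to 35430055) and H2-Q7 (35439155 to 35443773) are neighbours on chromosome 17. They are near-identical in sequence, so the split between them is uncertain, while the sum over the 8 H2-Q genes tested was 353 ± 9.78 CPM in Control and 504 ± 9.57 CPM in CUMS (94.9 and 210 CPM without H2-Q10). Rps27rt, a retrogene copy of a ribosomal protein gene, rose by 1.59 ± 0.17 and is uncertain for the same reason.

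The largest falls were in a pair of genes on chromosome 16. Sema5b, a semaphorin gene (35541145 to 35664732), measured 3.70 ± 0.341 CPM in Control and was listed at 0 in all 3 CUMS libraries, at least 30.7-fold lower against a floor of 3 read pairs per library (0.120 CPM; adjusted p = 5.2e-06). Slc15a2, a peptide transporter gene (36750177 to 36784962), at 11.1 ± 1.59 CPM in Control, fell 9.57-fold (log2 fold change -3.25 ± 0.21, adjusted p = 1.2e-05). Igfbp6, an insulin-like growth factor binding protein gene, fell by 2.23 ± 0.29 on the log2 scale, and Fdps, which makes farnesyl diphosphate in the mevalonate pathway, by 1.29 ± 0.14. Coq10b, a coenzyme Q binding protein gene, fell by 1.24 ± 0.085, Shcbp1 by 1.20 ± 0.20 and the glucuronosyltransferase gene Ugt1a6b by 1.79 ± 0.36. The call of Ugt1a6b, a member of a locus with shared exons, ended without Control replicate 2, CUMS replicate 2 or CUMS replicate 3 (adjusted p 0.065 to 0.097). Its Control libraries were uneven (4.31 ± 2.58 CPM, against 1.25 ± 0.334 CPM in CUMS), and without Control replicate 2, at 7.29 CPM, its log2 fold change was -1.17.

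**Figure D2:**
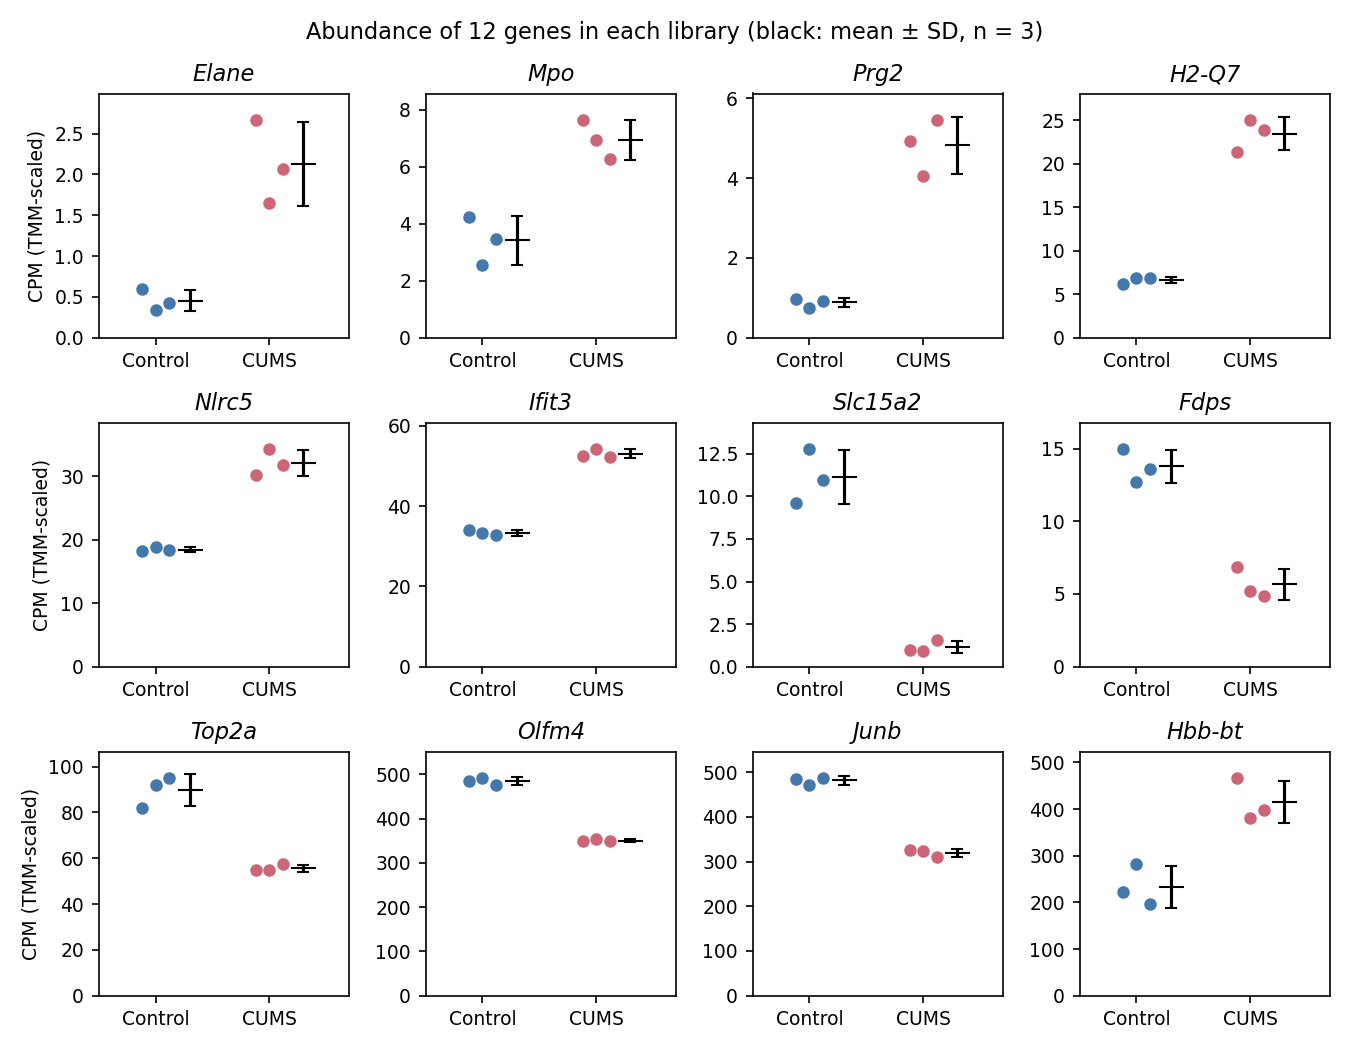
CPM (TMM-scaled) of 12 genes on linear axes that start at 0. Coloured points are single libraries (3 Control, 3 CUMS) and black marks the mean ± SD. The groups do not overlap for any of the 12; for Elane the Control libraries lie between 0.339 and 0.599 CPM and the CUMS libraries between 1.65 and 2.67 CPM.

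**Figure D3:**
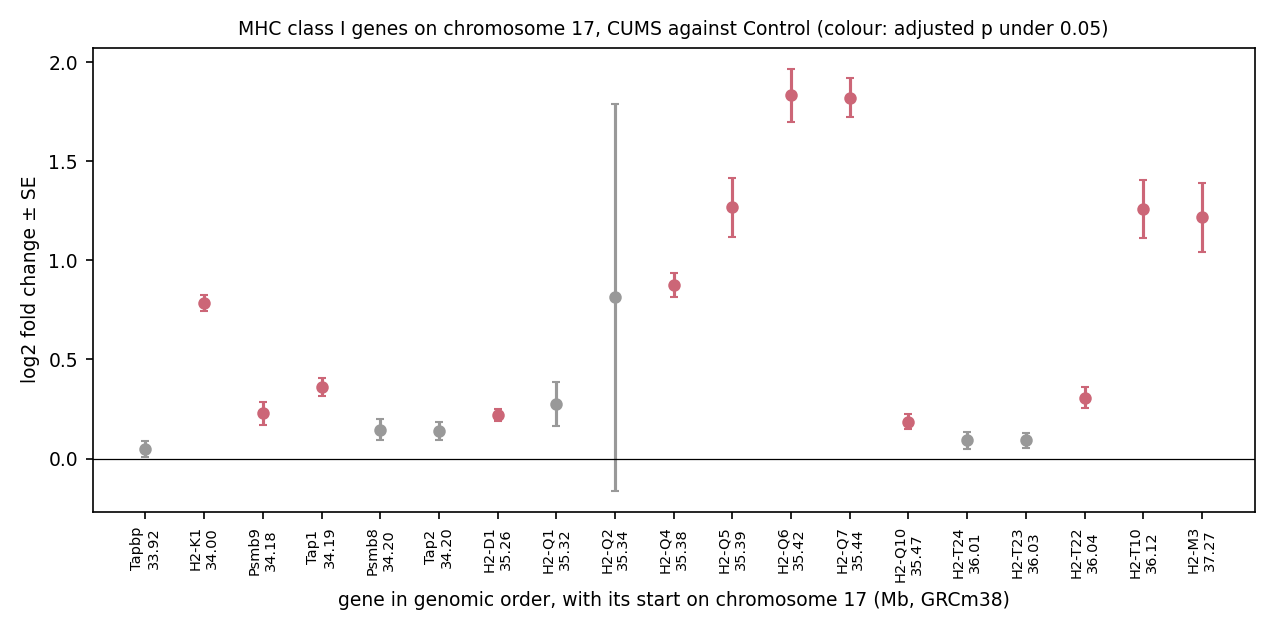
Log2 fold change ± SE (y axis) of MHC class I presentation genes on chromosome 17 in genomic order (x axis, start in Mb, GRCm38), a list chosen after the values were seen. Red marks an adjusted p under 0.05. H2-Q6 and H2-Q7 stand at 1.83 and 1.82 and H2-K1 at 0.79, while H2-D1 stands at 0.22.

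The granule programme of neutrophils did not move as a block. Of 13 primary granule genes tested, 3 rose (Elane, Mpo and Ctsd), 1 fell (Ctsc) and 9 did not pass. The counts were the same adjusted over the list alone. Mpo, the myeloperoxidase gene, rose from 3.42 ± 0.852 to 6.95 ± 0.70 CPM (SD, n = 3 each; log2 fold change 1.03 ± 0.19, adjusted p = 0.0095), and Ctsc, the cathepsin C gene whose product activates the granule serine proteases, fell by 0.99 ± 0.11. Ctsd rose by 0.18, a call that ended without Control replicate 2 or 3 (adjusted p 0.055 to 0.070). Prtn3 and Ctsg, the other major serine proteases of these granules, had log2 fold changes of 0.31 ± 0.33 and 0.78 ± 0.46, neither past the threshold (adjusted p = 0.73 and 0.43). As a list, the primary granule genes were not called (median 0.02, camera adjusted p = 0.39). Of 18 secondary granule genes, 5 fell and 0 rose (9 fell adjusted over the list alone), and all 18 were lower in CUMS. Olfm4 fell by 0.47 ± 0.036 from 485 to 350 CPM, Fcnb by 0.58 ± 0.058 and Chil3 by 0.32 ± 0.047. Ltf, the lactoferrin gene (-0.11), and Camp (-0.27) lost their calls without any single library other than CUMS replicate 1 (adjusted p 0.059 to 0.256 and 0.092 to 0.209), and both lost them with RLE scaling (0.060 and 0.050). Camera called the list down (median -0.15, adjusted p = 3.5e-10), but not with an estimated correlation (adjusted p = 0.17). In these same libraries the erythroid markers had a median of 0.94.

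Of 14 tertiary granule and secretory vesicle genes, Mmp9 rose by 0.12 ± 0.029 and Cd14, the lipopolysaccharide co-receptor gene, fell by 0.59 ± 0.079, with the same counts adjusted over the list alone. The list was not called (camera adjusted p = 0.72), its median (0.04) and mean (-0.0015) differing in sign. Of 20 genes of mature neutrophils, Mmp9 rose and Clec4e (-0.31 ± 0.049), Csf2rb (-0.20 ± 0.037) and Mxd1 (-0.13 ± 0.031) fell; adjusted over the list alone, 3 rose and 3 fell. The list was not called (median -0.03, adjusted p = 0.23), although without CUMS replicate 1 it was called down (adjusted p = 7.5e-04). S100a8, an alarmin gene, measured 19254 ± 455 CPM in Control and 15118 ± 4110 CPM in CUMS, where CUMS replicate 1 held 19775 CPM (log2 fold change -0.35 ± 0.13, adjusted p = 0.20). Without that library its log2 fold change was -0.59, with an adjusted p of 2.0e-04. With all 6 libraries S100a8 also passed with the replicate block (-0.38, 0.043), with the block and a GC correction (-0.37, 0.035) and with voom quality weights (-0.44, 0.025). Its adjusted p over the 21 alternatives ran from 2.0e-04 to 0.50. Mmp9 and Mxd1 lost their calls without Control replicate 2, Control replicate 3, CUMS replicate 2 or CUMS replicate 3 (adjusted p 0.0996 to 0.184 and 0.088 to 0.168), and Csf2rb without Control replicate 2, Control replicate 3 or CUMS replicate 3 (0.066 to 0.084). Of 18 granulocyte progenitor genes, Runx1 rose by 0.29 ± 0.052 and Fcnb fell (3 and 1 adjusted over the list alone). The list was not called (median 0.09, adjusted p = 0.69), and the Runx1 call ended without Control replicate 2 or CUMS replicate 3 (0.055 to 0.056).

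Cell division genes were lower in CUMS. Of 42 genes tested, 24 fell and 0 rose (32 and 0 adjusted over the list alone), with a median log2 fold change of -0.64. Camera called the list down (adjusted p = 2.9e-39), also with an estimated correlation (adjusted p = 0.0056). Top2a, the topoisomerase gene of dividing cells, fell from 89.6 ± 6.92 to 55.7 ± 1.51 CPM (log2 fold change -0.69 ± 0.061, adjusted p = 8.8e-05). The mitotic kinesin gene Kif11 fell by 0.71 ± 0.077, the spindle gene Tpx2 by 0.69 ± 0.077 and the mitotic kinase gene Cdk1 by 0.93 ± 0.11. In these same libraries the erythroid, B cell and plasma cell markers had medians of 0.94, 0.39 and 0.40.

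Interferon-response genes were higher in CUMS. Of 40 tested, 13 rose and 1 fell (20 and 2 adjusted over the list alone), with 35 higher in CUMS and a median of 0.16. Camera called the list up (adjusted p = 3.3e-12), also with an estimated correlation (adjusted p = 0.020). Ifit3 rose from 33.4 ± 0.667 to 53.1 ± 1.10 CPM (log2 fold change 0.67 ± 0.055, adjusted p = 5.1e-05). Its near-identical copy Ifit3b rose by 0.55 ± 0.061 and the antiviral gene Rsad2 by 0.39 ± 0.041. Ifitm6 was the member that fell (-0.32), a call that ended without any single library other than CUMS replicate 1 (adjusted p 0.050 to 0.102). In these same libraries the erythroid, B cell, plasma cell and monocyte markers had medians of 0.94, 0.39, 0.40 and 0.23.

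More immediate early genes fell than rose, and inflammatory genes moved both ways. Of 28 immediate early genes, 10 fell and Klf6 rose (11 fell and 5 rose adjusted over the list alone). Junb, an AP-1 subunit gene, fell from 482 ± 9.20 to 320 ± 8.96 CPM (log2 fold change -0.59 ± 0.039, adjusted p = 1.2e-05), the mRNA-decay factor gene Zfp36 by 0.37 ± 0.044 and Btg2 by 0.32 ± 0.039. The list was called down (median -0.19, adjusted p = 1.1e-05), but not with an estimated correlation (adjusted p = 0.054). Of 33 inflammatory cytokine and NF-kB genes, 4 fell (Tlr2, Osm, Cxcl2 and Il1b) and 4 rose (Ccl3, Ccl6, Nlrp3 and Gsdmd); adjusted over the list alone 9 fell and 4 rose. Tlr2 fell by 0.58 ± 0.039, Osm by 0.54 ± 0.046, the chemokine gene Cxcl2 by 0.51 ± 0.054 and Il1b by 0.35 ± 0.044, while Ccl3 rose by 0.55 ± 0.12, Ccl6 by 0.35 ± 0.063, the inflammasome gene Nlrp3 by 0.31 ± 0.045 and Gsdmd by 0.21 ± 0.053. This list was called down (median -0.02, adjusted p = 0.0094), but not with an estimated correlation (adjusted p = 0.13) and not without CUMS replicate 2 (0.071). Without a single library the calls ended for Klf6 (Control replicate 2 or 3, CUMS replicate 2 or 3, adjusted p 0.055 to 0.105), Ccl6 (Control replicate 2 or 3, 0.0515 each), and Ccl3 and Gsdmd (any library other than CUMS replicate 1, 0.062 to 0.112 and 0.067 to 0.191).

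Genes that respond to glucocorticoids showed no common direction. Of 21 tested, 4 rose (Fkbp5 by 0.28, Zbtb16 by 0.49, Sgk1 by 0.23 and Cxcr4 by 0.25 ± 0.044) and 3 fell (Zfp36, Per1 and Cdkn1a, the last by 0.76); adjusted over the list alone, 6 rose and 5 fell. The list was not called (median -0.03, adjusted p = 0.88). Of 12 stress hormone receptor genes, 3 were tested with edgeR and 0 passed (1 at an unadjusted p under 0.05, 1 with DESeq2). The glucocorticoid receptor gene Nr3c1 measured 239 and 249 CPM (log2 fold change 0.06 ± 0.052, adjusted p = 0.64). Adjusted over the list alone, 1 gene of these 3 rose, and the list was not called (adjusted p = 0.12). Of 15 circadian clock genes, Per1 (-0.33 ± 0.051) and Nfil3 (-0.36 ± 0.055) fell and 0 rose (2 and 1 adjusted over the list alone), and camera did not call the list (median -0.12, adjusted p = 0.135), while fry called it down (0.015). The calls ended without Control replicate 2 or CUMS replicate 2 for Fkbp5 (0.059 to 0.061), without Control replicate 1, Control replicate 2, CUMS replicate 2 or CUMS replicate 3 for Zbtb16 (0.070 to 0.114), without any library other than CUMS replicate 2 for Sgk1 (0.051 to 0.128) and without any library other than CUMS replicate 1 for Cdkn1a (0.058 to 0.134).

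Trafficking genes moved little. Of 28 tested, Jaml, a junctional adhesion protein gene, rose by 0.33 ± 0.046, Cxcr4, the receptor that holds neutrophils in the marrow, by 0.25 ± 0.044 from 407 to 484 CPM, and Ptafr by 0.22, while Ccrl2 fell by 0.43 ± 0.075 (6 rose and 1 fell adjusted over the list alone). The list was not called (median 0.04, adjusted p = 0.13), though it was called up without Control replicate 1 or CUMS replicate 2 (0.030 to 0.035). The Ptafr call ended without Control replicate 3, CUMS replicate 2 or CUMS replicate 3 (0.054 to 0.071). Of 16 genes of the NADPH oxidase and of extracellular traps, 4 rose (Elane, Mpo, Gsdmd and Ncf1) and 0 fell (5 and 0 adjusted over the list alone). Ncf1, an oxidase subunit gene, rose by 0.14 ± 0.030. Camera called this list up (median 0.03, adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.50), not with fry (0.13), and not without Control replicate 3 or CUMS replicate 1 (0.088 to 0.098). Ncf1 lost its call without Control replicate 2, Control replicate 3, CUMS replicate 2 or CUMS replicate 3 (0.061 to 0.126), and Gsdmd without any library other than CUMS replicate 1 (0.067 to 0.191).

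Metabolic and protein-folding lists were lower by small amounts. Of 21 glycolysis genes, 5 fell and 0 rose (11 and 1 adjusted over the list alone): the glucose transporter gene Slc2a1 by 0.54 ± 0.052, Pfkfb3 by 0.29 ± 0.045, Ldha by 0.27 ± 0.044, Tpi1 by 0.30 and Slc16a3 by 0.24. The list was called down (median -0.11, adjusted p = 2.7e-06), but not with an estimated correlation (adjusted p = 0.054). Of 25 genes of the unfolded protein response and amino acid stress, 5 fell and 0 rose (7 and 0 adjusted over the list alone): Pdia3 by 0.31 ± 0.045, Xbp1 by 0.29 ± 0.049, Hsp90b1 by 0.28 ± 0.048, Hyou1 by 0.35 and Canx by 0.21. That list was called down (median -0.20, adjusted p = 1.6e-05), but not with an estimated correlation (adjusted p = 0.13). With edgeR and TMM scaling no gene passed among the 57 nuclear genes of the respiratory chain (Atp5b -0.13 ± 0.044, Atp5a1 -0.07 ± 0.043), the 13 mitochondrially encoded genes (COX1 -0.19 ± 0.050, COX2 -0.19 ± 0.091) or the 79 ribosomal protein genes (Rps9 0.02 ± 0.051, Fau 0.04 ± 0.065). Adjusted over the list alone, 0, 1 and 0 fell and 0 rose. An unadjusted p under 0.05 was seen for 7, 5 and 3 genes of these lists, and DESeq2 called 1, 2 and 1. COX1 (adjusted p = 0.059) passed in 10 of 20 alternatives, 7 of them edgeR fits: library totals (0.043), the 1 CPM filter (0.031), the length correction (0.030), the replicate block (0.0092), the block with a GC correction (0.0060), values divided by 4 (0.032) and the fit without CUMS replicate 1 (0.0054). It also passed with DESeq2 (0.0038) and with voom without and with quality weights (0.021 and 0.0081), over a range of 0.0038 to 0.26 in the 20. Camera called the first 2 of these lists down (medians -0.12 and -0.15, adjusted p = 4.0e-04 and 0.0045), but neither with an estimated correlation (adjusted p = 0.53 each) nor with fry (0.25 and 0.24), and did not call the ribosomal list (median -0.004, adjusted p = 0.88). The mitochondrially encoded list was not called without CUMS replicate 2 (0.106). Without CUMS replicate 1, the ribosomal list was called down (5.7e-05) and COX2 passed (0.031). Single libraries also ended the calls of Tpi1 (any other than CUMS replicate 1, 0.061 to 0.10), Slc16a3 (CUMS replicate 3, 0.056), Canx (any library, 0.056 to 0.156) and Hyou1 (Control replicate 2, Control replicate 3, CUMS replicate 1 or CUMS replicate 2, 0.051 to 0.093).

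Some markers of other marrow cells rose. Of 18 erythroid markers, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.94. The haem synthesis gene Alas2 rose from 23.5 ± 5.01 to 46.8 ± 4.32 CPM (log2 fold change 0.99 ± 0.13, adjusted p = 0.0011), the anion exchanger gene Slc4a1 by 1.20 ± 0.15 and the haemoglobin gene Hbb-bt by 0.83 ± 0.11. Camera called the list up (adjusted p = 7.6e-20), but not with an estimated correlation (adjusted p = 0.054). All 19 B cell markers were higher in CUMS (median 0.39), of which Ighm rose by 0.31 ± 0.042 from 141 to 175 CPM and 0 fell (3 and 0 adjusted over the list alone). Of 9 plasma cell markers Igha rose by 0.40 ± 0.099 and 0 fell (2 and 0 adjusted over the list alone; median 0.40). Both lists were called up (adjusted p = 8.4e-05 and 0.0035), but not with an estimated correlation (adjusted p = 0.073 and 0.11). The plasma cell list also lost its call with a filter of 1 CPM (0.053), and the Igha call ended without any single library (0.055 to 0.179). Of 23 monocyte and macrophage markers, 4 rose and 0 fell, the same adjusted over the list alone: the iron exporter gene Slc40a1 by 0.33 ± 0.036, Fn1 by 1.38 ± 0.19, F13a1 by 1.34 ± 0.23 and Csf1r by 0.19. Slc40a1 measured 415 CPM in Control and 523 CPM in CUMS, far above the median level of the list, 0.62 CPM. The list was called up (median 0.23, adjusted p = 0.0089), but not with an estimated correlation (adjusted p = 0.32), not with fry (0.090), and not without Control replicate 3 or CUMS replicate 1 (0.055 to 0.111). The Csf1r call ended without any single library other than CUMS replicate 1 (0.058 to 0.114).

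Of 18 eosinophil, basophil and mast cell markers, Prg2 and Epx rose and Hdc, the histidine decarboxylase gene, fell by 0.35 ± 0.034 from 1051 to 826 CPM (4 rose and 3 fell adjusted over the list alone). Epx, the eosinophil peroxidase gene, went from 0.119 ± 0.110 CPM, about the floor of 3 read pairs (0.109 to 0.152 CPM per library), to 1.49 ± 0.148 CPM (log2 fold change 3.68 ± 0.73, adjusted p = 0.016). Its call ended without Control replicate 3, CUMS replicate 2 or CUMS replicate 3 (0.063 to 0.071). Its log2 fold change was 4.46 without Control replicate 1 and 3.06 without Control replicate 2, and up to 5.52 over all alternatives. The list was not called (adjusted p = 0.45), its median of -0.04 and mean of 0.38 differing in sign. Of 14 dendritic cell and MHC class II markers, 0 passed with edgeR, also adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (Cd74 0.08 ± 0.091, Tcf4 -0.22 ± 0.17; median 0.04, list adjusted p = 0.395). Of 11 T and NK cell markers, 0 passed with edgeR either way, 1 had an unadjusted p under 0.05 and DESeq2 called 0 (Cd3d -0.05 ± 0.21, Il7r 0.24 ± 0.36), and the list was not called (adjusted p = 0.96), with a median of 0.14 and a mean of -0.17. Of 8 megakaryocyte and platelet markers, Thbs1 fell by 0.29 ± 0.039, 0 rose, and the counts were the same adjusted over the list alone (median -0.03, list adjusted p = 0.39). Of the 4 stromal and endothelial markers tested, 0 passed with edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 1 (Col1a1), while 2 rose and 1 fell adjusted over the list alone (Col1a1 0.57 ± 0.17, adjusted p = 0.083; Cxcl12 1.13 ± 0.47, adjusted p = 0.24; median 0.85, list adjusted p = 0.30). Col1a1 also passed without CUMS replicate 1 (0.049), with voom quality weights (0.045) and with the replicate block and a GC correction (0.049).

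In all, camera called 14 of the 28 lists, 6 up and 8 down, and 2 of these calls (cell cycle and interferon response) held with an estimated correlation. Fry called 11 lists, 10 of them among the 14.

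**Figure D4:**
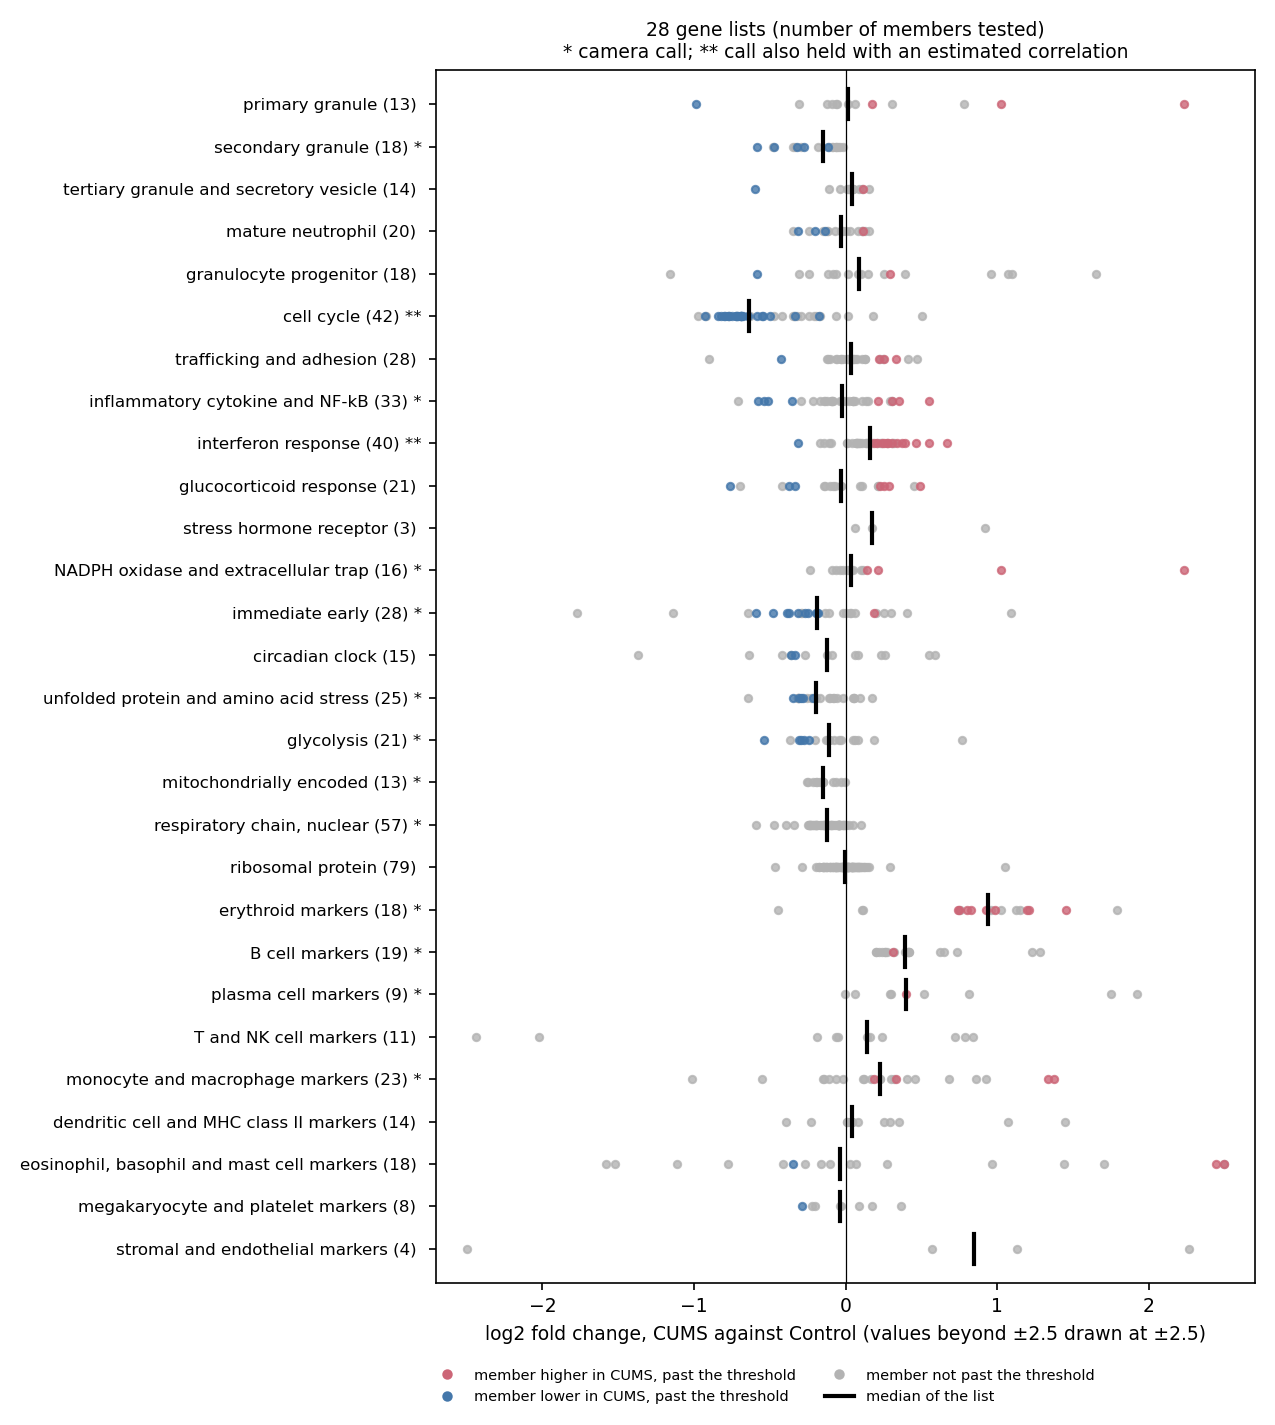
Log2 fold change (CUMS against Control, x axis) of every tested member of 28 gene lists (y axis, number of members in brackets), with values beyond ±2.5 drawn at ±2.5. Coloured points passed the threshold (red higher, blue lower in CUMS), grey points did not, and black bars are list medians, from -0.64 for the cell cycle to 0.94 for erythroid markers. Asterisks mark lists called by camera, and double asterisks the 2 lists also called with an estimated correlation.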

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

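The values divided by 4, the lists on cholesterol and MHC class I and the genes added to the rule were chosen after the data were seen; all other alternatives were fixed in advance. Elane was called higher in CUMS in all 21 alternative fits, with log2 fold changes from 2.03 to 2.48, both of them fits without a single library (CUMS replicate 1 and Control replicate 1), and adjusted p from 2.6e-07 to 0.017. Against the 710 genes called, alternatives called 462 (all of them among the 710) with no filter beyond 1 count (23638 genes tested, more than the 15778 of the filtered fit), 1146 with DESeq2 (688 among the 710), 1078 and 275 at adjusted p under 0.1 and 0.01, and 81 with a log2 fold change of at least 1. With the values divided by 4, 895 genes were called (461 higher, 434 lower), 693 of them among the 710, with 12857 genes tested. The count was 305 to 697 with a library left out, where fewer samples were fitted, and the cause of the DESeq2 count was not tested. Libraries with the same replicate number did not deviate together (correlations of 0.008, 0.003 and -0.026), and 1 of 6 libraries correlated best with its own number: with the replicate block, 931 genes were called, 684 of them among the 710, and 1066 with the block and a GC correction. With the block, 14 lists were called, as without it. The first principal component held 29.7 to 32.4% of the variance with a library left out and kept the groups apart. An estimated correlation left 2 of 14 list calls. Fry called 11 lists, 10 of them among the 14: it added the circadian clock (adjusted p 0.015) and dropped the mitochondrially encoded (0.24), respiratory chain (0.25), monocyte (0.090) and NADPH oxidase (0.13) lists. Single libraries left out gave 12 to 15. Among lists not called in any of these fits, the direction turned for T and NK cell markers with fry (adjusted p 0.975), RLE scaling (0.999), GC correction (0.995) and without Control replicate 1, Control replicate 3 or CUMS replicate 1 (0.656 to 0.778, with up to 0.873 over the 6 fits without 1 library), and for granulocyte progenitors with the 1 CPM filter (0.925) and division by 4 (0.932). It also turned in fits without 1 library for glucocorticoid response (range over the 6 fits 0.60 to 0.983), primary granule (0.196 to 0.788), tertiary granule (0.397 to 0.995) and ribosomal protein genes (5.7e-05 to 0.882, the lowest a call without CUMS replicate 1). Genes not past the threshold whose sign turned were Il7r (-0.020 with voom quality weights, -0.27 to 0.46 with a library left out), Cd3d (-0.21 to 0.13 with a library left out), Rps9 (-0.033 to 0.053 likewise, 0.063 with a length correction) and Fau (-0.041 to 0.090 likewise, 0.106 with a length correction). The calls of 99 genes, named by the rule or chosen after their values were seen, were checked in every fit that tested them. Of these, 69 kept the call and 30 lost it in at least 1 fit, none with a change of sign. The cause was not tested. The 99 favour large changes and small adjusted p, so they do not stand for all 710. With a single library left out, 293 (CUMS replicate 3) to 532 (CUMS replicate 1) of the 710 were called again. At this depth, 3 read pairs equal 0.109 to 0.152 CPM per library, and differences between levels below that are not detectable.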

Other observations

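The lists of cholesterol and MHC class I genes were chosen after the values were seen, as were the tests on progenitor granule genes, on sort purity, on neighbouring genes, on the H2-Q sum and on secondary granule genes; the tests on Nlrc5, on GC content and on splits of the libraries were set out before their results were seen. Of 24 genes of cholesterol synthesis and uptake tested, 15 fell and 0 rose (19 and 1 adjusted over the list alone), with a median log2 fold change of -0.69. The marker lists of other cell types had medians from -0.04 (eosinophil) to 0.94 (erythroid) in these same libraries. Cyp51, the lanosterol demethylase gene, fell from 16.3 ± 1.14 to 7.14 ± 0.504 CPM (SD, n = 3 each; log2 fold change -1.19 ± 0.11, adjusted p = 8.8e-05). The squalene epoxidase gene Sqle fell by 0.98 ± 0.17 and Fdps by 1.29 ± 0.14.

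Genes of MHC class I presentation rose unevenly. Of 26 tested, 14 rose and 0 fell (18 and 0 adjusted over the list alone), and all 26 were higher in CUMS (median 0.25). The list holds H2 class I genes and also other genes of the pathway, such as B2m, Tap1 and Nlrc5. Medians of the 9 marker lists of other cell types ran from -0.04 (eosinophil) to 0.94 (erythroid) in these same libraries. The B cell, plasma cell and monocyte lists stood at 0.39, 0.40 and 0.23. H2-K1, a classical class I gene, rose from 408 ± 14.4 to 702 ± 11.1 CPM (log2 fold change 0.79 ± 0.039), while the other classical gene, H2-D1, rose by 0.22 ± 0.031 from 2314 CPM. H2-Q4, H2-T10 and H2-M3 rose by 0.87 ± 0.060, 1.26 ± 0.15 and 1.22 ± 0.18, the peptide transporter gene Tap1 by 0.36 ± 0.045, and Nlrc5, the transactivator of class I genes, by 0.80 ± 0.071 (18.4 ± 0.342 to 32.1 ± 2.07 CPM). Nlrc5 starts at 94.434356 Mb on chromosome 8. Its neighbours Slc12a3 (94329201 to 94366214) and 9330175E14Rik (94422898 to 94435103) rose by 1.25 and 1.65. The Slc12a3 call ended without CUMS replicate 2 (adjusted p 0.058). 9330175E14Rik overlaps the start of Nlrc5, so reads there may not be told apart. B2m, the light chain gene, had a log2 fold change of 0.20 ± 0.075 (adjusted p = 0.20) and passed in 3 of 21 alternatives: a length correction (0.0060), the replicate block (0.023) and the block with a GC correction (0.010), over a range of 0.0060 to 0.41.

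The real split of the 6 libraries gave 710 genes and the highest of the other 9 splits gave 1. Each of those 9 mixes Control and CUMS libraries on both sides, so a group difference adds to the spread within a side and lowers the count. Their counts therefore do not measure the number of false calls. Only 1 of the 10 splits, the real one, reached that count, and 10 splits are too few for a share under 0.05.

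Higher Elane in CUMS was set against 2 changes in the cells sorted. More granulocyte progenitors could raise other genes of progenitor granules with it. The 6 such genes tested (Mpo, Prtn3, Ctsg, Prss57, Ms4a3 and Ctsc) had a median log2 fold change of 0.093 (SE 0.39 between genes). Its upper bound of 0.87 lies under the lower bound for Elane, 1.58, but this cannot decide the question. A fold change depends on the level at the start, and Control means were 0.454 CPM for Elane but 9.29 for Prss57 and 13.1 for Ctsc. The 6 genes also went both ways, from -0.99 (Ctsc) to 1.03 (Mpo). The list of 18 granulocyte progenitor genes fixed in advance had a median of 0.09 (SE 0.12 between genes, upper bound 0.34). Of these 18, 3 rose and 1 fell adjusted over the list alone, and some members, such as Cebpe (159 CPM in Control), were abundant in the sorted cells. More progenitors, or a change in part of them, therefore stay open. For the purity of the sort, the form tested was a fall that raises markers of all 9 other cell types alike and as much as Elane. The median of each of the 9 marker lists was taken per library, and the lists changed by -0.052 to 0.84. The highest upper bound of the 9 (2 SE) was 1.40, also under 1.58. These bounds do not exclude a lower purity in other forms, since a rise depends on which cells pass the sort and on each marker's starting level. With 3 libraries per group, 2 SE also falls short of the usual confidence bound. Of the 9 lists, 6 rose by more than 2 SE (erythroid, B cell, plasma cell, monocyte, dendritic and stromal). Departures from the mean of the other lists were tested with an equal-variance t test on the scores of the 6 libraries, adjusted over the 9 lists. The platelet list departed by -0.45 ± 0.077 (adjusted p = 0.038) and the erythroid list by 0.55 ± 0.14 (adjusted p = 0.086). The platelet value cannot decide on an equal rise of all 9 types, since its member Thbs1 already stood at 2214 CPM in Control. More RNA of the types that rose stays open: none of the 18 erythroid markers is held by another list, and Hbb-bs rose from 523 ± 106 to 913 ± 92.8 CPM and Hba-a1 from 439 ± 76.6 to 736 ± 70.8 CPM in cells that a flow cytometry sort should have separated from red cells. Prg2, of the eosinophil list, rose by 2.45, as much as Elane, and Epx rose from about the floor to 1.49 CPM, so rare cells that hold these transcripts also stay open as a source of Elane. An effect of stress on Elane within neutrophils was not tested and would need sorted stages or single cells.

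Large changes in neighbouring genes, such as Sema5b with Slc15a2, Slc12a3 with 9330175E14Rik beside Nlrc5, and the H2-Q genes, may reflect a difference in genetic background between the groups. Genes changed at least 2-fold lay within 2 Mb of another such gene in 14 of 69 cases with coordinates, against a median of 12 in 2000 random draws of matched expression (permutation p = 0.34). Pairs whose symbols start with the same letters (the H2 genes too) were not counted, but the peroxidase genes Mpo and Epx were. Background and stress therefore cannot be told apart for these genes, since the strain and litters of the mice are not given in the sources used here. Reads moved among the near-identical H2-Q genes would leave their sum level, but it rose by 0.51 (SE 0.028) on the log2 scale. Higher Nlrc5 acting on class I genes wherever they lie was predicted to raise B2m, Psmb10, Erap1, Psme1 and Psme2 too. Their median was 0.069 (SE 0.048 between genes, not libraries), with an interval from -0.026 to 0.16 that includes 0. As a set these 5 genes therefore did not rise as much as Nlrc5 (0.80) or H2-K1 (0.79). Whether Nlrc5 acts on each of the 5 was not tested, so their median does not decide on Nlrc5 as a cause. For B2m alone (0.20), for H2-K1 and for the H2-Q genes that cause stays open.

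Lower cell cycle genes did not follow from GC content. The median of the list was -0.64 (SE 0.074 between genes) before and -0.63 (SE 0.072 between genes) after a GC correction. That correction moved single genes by up to 0.071, and camera still called the list. Fewer dividing precursors among the sorted CUMS cells may be a candidate explanation. The list of secondary granule genes, which are made in myelocytes, was called down too (camera adjusted p = 3.5e-10), but not with an estimated correlation (adjusted p = 0.17), and Elane and Mpo, made in dividing promyelocytes, rose. Fewer precursors and slower division therefore cannot be told apart from these libraries. An effect of stress itself on division was not tested apart from the group difference.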
